A study of Drosophila melanogaster with 62 samples.

How the data were processed

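Fat bodies of wandering third-instar larvae were profiled by RNA-seq in 62 samples of 4 experiments: cg-GAL4 males (control and Tfb1 RNAi), cg-GAL4 females (control), r4-GAL4 females with the w1118 control stock and r4-GAL4 females with the 60100 control stock (control and FOXO, p53 or Stat92E RNAi). Per the labels, male tissue was dissected, female tissue was floated (sheared and separated by centrifugation), and total RNA was depleted of ribosomal RNA with RiboZero and sequenced on an Illumina HiSeq. The submitters' processing notes name TopHat 1.3.2 with Bowtie 0.12.7 for alignment to the dm3 genome and Cufflinks 1.1.0 for expression values. The deposited table holds FPKM values, fragments per kilobase of transcript relative to the depth of the library, for 14659 genes in 61 columns. The labels list 4 samples for p53 RNAi at 0.15 M and the table has 3 columns for that group, so its comparisons are 3 against 4 libraries. Of the columns, 18 (cg females and r4 w1118 females) were matched to samples by title, and 43 were matched to a group only; within those groups the library numbers used here follow column order and serve as names. Headings in the male groups and p53 RNAi at 0.15 M also end in a number, 1 to 3, the same as column order. Headings of the male columns carry r4 or D2 where the labels say cg-GAL4 males; the labels were followed.

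The values were checked before use. In every library of an experiment the same number of genes reached 1 (2080 in cg females, 2464 or 2465 in r4 60100 females, 2117 in r4 w1118 females and 2649 in cg males). The value at that rank was 1.00 within rounding, so each library had been scaled to a fixed rank, a step that the labels do not state. The values are therefore called scaled FPKM and are relative within an experiment. Depth was estimated from the lower edge of value times transcript length in each library. If that edge is 1 fragment, a value of 1 in a transcript of 1 kb stands for 4.85 to 8.16 fragments in cg females, 6.29 to 25.2 in r4 60100 females, 3.15 to 10.6 in r4 w1118 females and 2.22 to 7.48 in cg males. Values near 1 thus rest on few fragments, and no counts were used.

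Differences were fitted with limma 3.58.1 in R 4.3.3 (linear model per gene, empirical Bayes with a mean-variance trend) on log2 of scaled FPKM with a pseudocount of 1, each experiment alone with a mean per group, over genes with a mean of at least 1 in the experiment's libraries. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. The comparisons were each high-sugar diet against 0.15 M in controls, a linear trend on the sucrose concentration over 4 diets in r4 w1118 females, each RNAi against its control at each diet, and the difference of the RNAi effect between diets. The genes called in the same direction in the 3 female comparisons of 0.7 M with 0.15 M, which share no libraries, were counted beside the number that independent lists would share. The p-values measure the spread between these libraries only, since the labels do not say whether libraries came from separate sets of animals.

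The targeted genes and Dcr-2 were tested by exact two-sided permutation of the libraries' group labels on the log2 scale, because foxo, p53 and Tfb1 lay below the filter. Smallest possible values are 0.1 for 3 against 3 libraries and 0.029 for 4 against 4 or 3 against 4. For 40 gene lists (pathways, complexes and markers of other cells; 789 members written, 778 found) members called were counted over all genes tested and with p-values adjusted over the list alone. Lists with at least 5 tested members were also tested against other genes with limma's camera, at a preset correlation between genes of 0.01 and again with the correlation estimated for each list, adjusted over the lists of a comparison. With the preset correlation 119 list tests passed, and 4 of them with the estimated one: antimicrobial peptides and immune signalling in p53 RNAi at 0.15 M, storage genes in p53 RNAi at 0.7 M and immune signalling in the p53 difference between diets.

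The comparisons, lists, filter, threshold and the rule for named genes were fixed before the data were examined. The rule names the targeted genes and up to 4 called members per list in order of absolute change, or 2 where none was called. It adds, among called genes with a mean of at least 5 in either group and no overlap between the groups' libraries, the 8 largest rises and falls per diet comparison and the 5 per RNAi comparison. For a difference between diets it takes the 3 largest without the condition on overlap, and for the shared genes the 8 highest and lowest. The text stops early in some lists and keeps the order. For 3 against 3 libraries chance gives no overlap in 10% of genes. Alternatives were a pseudocount of 0.1, no filter on low values, rescaling each library by its median ratio to the experiment's geometric mean, the replicate number as a block where titles give one, and one fit over all libraries. Others were each library left out in turn, a relaxed threshold for the shared genes and the estimated correlation for lists. Chosen after seeing the data were removal of each library's trend on transcript length (lowess, span 0.67, annotated lengths), the mean log2 level of the gut marker list as a covariate, and leaving out libraries whose correlation with their group lay more than 3 scaled MAD below the median. So were the number in the male headings and the column order in r4 60100 females as a block, each library left out for the shared and targeted genes, and the pseudocount of 0.1 and the rescaling for the targeted genes.

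The fit was tested on simulated normal values with the same groups and each gene's estimated spread, in which 200 genes were changed. At a log2 change of 1 it recovered 85.1% of changed genes in the male diet comparison, 89.6% in the cg female one and 86.6% in the r4 60100 one. It recovered 92.5% for FOXO RNAi at 0.7 M, 88.1% for p53 RNAi at 0.15 M, 56.7% for the Tfb1 difference between diets and 73.1% for the Stat92E difference. At a log2 change of 0.5 it recovered 35.8%, 47.8%, 61.2%, 50.7%, 61.2%, 13.4% and 29.9% in the same order. Of the genes it called, 10.9% were unchanged ones in the Tfb1 difference, above the 5% aimed at, and 0 to 5.39% in the other comparisons. Figures were drawn with matplotlib 3.10.9.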

Results

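RNA from the fat body of wandering third-instar Drosophila melanogaster larvae was sequenced after growth on semi-defined food with 0.15 M sucrose (the control diet), 0.3 M, 0.7 M or 1.0 M sucrose. All larvae carried UAS-Dcr2, a transgene used to strengthen RNAi, and a fat body driver, cg-GAL4 or r4-GAL4, crossed to a control stock of the VDRC (w1118 or 60100) or to an RNAi line. Per the labels, the purpose was to measure how diet and knockdown of transcription factors in the fat body alter gene expression. The 61 libraries form 18 groups in 4 experiments. The cg males held control and Tfb1 RNAi larvae at 0.15 M and 1.0 M (3 libraries per group), the cg females held control larvae at 0.15 M and 0.7 M (3 per group), and the r4 w1118 females held control larvae at all 4 diets (3 per group). The r4 60100 females held control, FOXO RNAi, p53 RNAi and Stat92E RNAi larvae at 0.15 M and 0.7 M (4 per group, but 3 for p53 RNAi at 0.15 M).

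Values were given for 14659 genes as scaled FPKM, a relative unit in each library. Totals per library were 29778.6 to 45721.5 in the cg females, 40335.5 to 76932.4 in the r4 60100 females, 38664.0 to 59268.6 in the r4 w1118 females and 25088.3 to 52391.7 in the cg males. Genes above 0 numbered 6500 to 7934, 7131 to 9108, 6152 to 7692 and 6662 to 10080 in the same order. The libraries were shallow: if the lowest values of a library stand for 1 fragment, a value of 1 in a transcript of 1 kb stands for 4.85 to 8.16, 6.29 to 25.2, 3.15 to 10.6 and 2.22 to 7.48 fragments. Below, a change is a difference of mean log2 (scaled FPKM + 1) with its standard error, and p-values are limma's, adjusted over the genes tested, unless called exact.

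The knockdown was read first in the targeted genes themselves. Stat92E (CG4257), the transcription factor of the JAK/STAT pathway, averaged 0.443 scaled FPKM (SD 0.15, n = 4) in Stat92E RNAi larvae against 2.68 (SD 1.1, n = 4) in controls at 0.15 M, which is 16.5% of control (exact two-sided permutation p = 0.029). At 0.7 M it averaged 0.233 (SD 0.094) against 0.98 (SD 0.35), or 23.8% (exact p = 0.029, the smallest that 4 against 4 allows). The transcript of foxo, the forkhead factor that insulin signalling restrains, averaged 0.34 (SD 0.065) against 0.599 (SD 0.12), or 56.9% of control, at 0.15 M (exact p = 0.029, n = 4 and 4). At 0.7 M it averaged 0.202 (SD 0.043) against 0.31 (SD 0.13), or 65% (exact p = 0.17). The p53 transcript averaged 0.0904 (SD 0.011, n = 3) against 0.126 (SD 0.026, n = 4), or 71.6%, at 0.15 M (exact p = 0.057, smallest possible 0.029) and 0.14 (SD 0.033) against 0.226 (SD 0.038), or 62.2%, at 0.7 M (exact p = 0.029). In the last result every RNAi library (0.0939 to 0.164) lay below every control (0.172 to 0.26). It missed 0.05 after rescaling by the median ratio, and limma with no filter gave adjusted p = 0.13. The exact p also missed 0.05 with any of the 4 RNAi libraries left out. The groups still did not overlap then, so that miss alone does not show a weaker change. Tfb1, a subunit of the general transcription and DNA repair factor TFIIH, averaged 0.467 (SD 0.1) against 0.819 (SD 0.21), or 57%, at 0.15 M and 0.446 (SD 0.033) against 0.608 (SD 0.079), or 73.4%, at 1.0 M. Both Tfb1 tests gave an exact p of 0.1, the smallest that 3 against 3 can give. Apart from Stat92E, these transcripts lay below the filter of a mean of 1 and rested on few fragments, 1.9 to 7.3 per library for p53 in p53 RNAi larvae and their controls and 1.7 to 9.2 for Tfb1.

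The transcripts of foxo and Stat92E were also low in some knockdowns that did not target them. At 0.15 M foxo averaged 0.272 (SD 0.035) in Stat92E RNAi, below the 0.34 in FOXO RNAi, and 0.45 (SD 0.1) in p53 RNAi. A lower foxo transcript was thus not particular to FOXO RNAi and cannot be read as its knockdown alone. Stat92E fell in FOXO RNAi at 0.15 M, where it averaged 1.21 (SD 0.62, change -0.73 ± 0.19, adjusted p = 0.0086). Library 2 had 2.14 and the others 0.854 to 0.936. At 0.7 M Stat92E averaged 0.917 in FOXO RNAi and 0.98 in controls. Library 2 of FOXO RNAi had 1.73 and the others 0.595 to 0.701, below every control. The foxo transcript averaged 0.268 in Stat92E RNAi, 0.184 in p53 RNAi, 0.202 in FOXO RNAi and 0.31 in controls at 0.7 M. In p53 RNAi Stat92E averaged 1.6 at 0.15 M (-0.48 ± 0.20, adjusted p = 0.23) and 0.452 at 0.7 M (-0.43 ± 0.19, adjusted p = 0.13), where every library (0.348 to 0.56) lay below every control (0.706 to 1.47). The p53 transcript was instead higher in FOXO RNAi at 0.7 M, at 0.443 to 0.638 against 0.172 to 0.26 in controls. It rested on 6.4 to 34 and 4.2 to 7.3 fragments per library. The Dcr-2 transcript, which includes any from the UAS-Dcr2 transgene, fell in Tfb1 RNAi from 96.7 to 27.1 at 0.15 M (-1.80 ± 0.16, adjusted p = 1.4e-05) and from 40.8 to 16.1 at 1.0 M (-1.3 ± 0.16, adjusted p = 2.3e-04), each with an exact p of 0.1, the smallest possible. In FOXO RNAi at 0.15 M it averaged 10.6 against 23.3 (-1.13 ± 0.39, adjusted p = 0.048, exact p = 0.086), and at 0.7 M 9.43 against 9.8 (exact p = 0.89). The mean at 0.7 M rests on library 2, which had 21.1 of Dcr-2, with 3.88 to 6.72 in the others. In p53 RNAi it averaged 11.8 at 0.15 M (exact p = 0.057) and 3.48 at 0.7 M, or 35.5% of control (-1.11 ± 0.39, adjusted p = 0.063, exact p = 0.029). In Stat92E RNAi it averaged 14.6 and 4.8 (exact p = 0.14 each). Dcr-2 was also lower in control larvae on high sugar, at 40.8 against 96.7 in cg males (-1.23) and 20.1 against 74.4 in cg females (-1.87). The white gene, an eye pigment transporter gene used to mark transgenes, rose in all 3 r4 RNAi lines, from 2.95 in controls to 19.2 (FOXO), 14.7 (p53) and 17.5 (Stat92E) at 0.15 M.

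**Figure D1:**
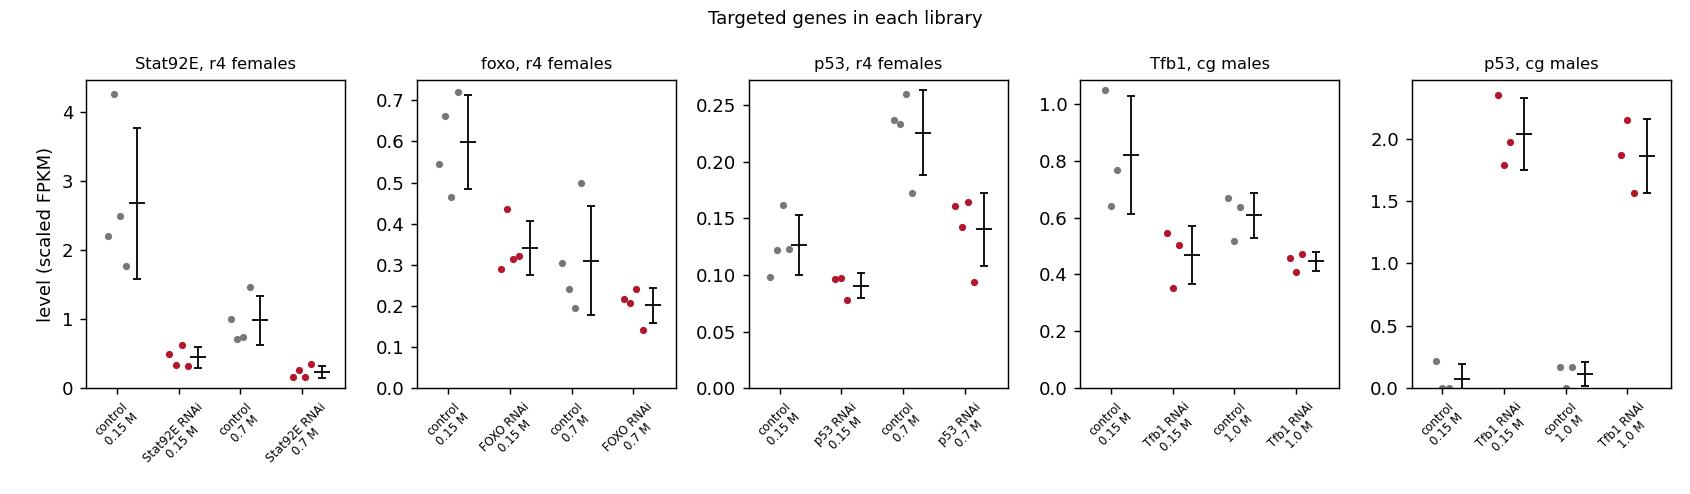
Scaled FPKM (y axis, from 0) of each targeted gene in its control and matching RNAi libraries, and of p53 in the cg males with control or Tfb1 RNAi. Libraries are shown as points by diet and genotype, with bars for the mean ± SD. Stat92E averaged 0.443 in Stat92E RNAi against 2.68 in controls at 0.15 M, and p53 in cg males averaged 2.04 in Tfb1 RNAi against 0.0717 in controls.

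In cg females, the first question was what 0.7 M sucrose does to fat body expression. Genes that make and store fat were higher on high sugar. Of 7 measured genes of fatty acid synthesis 5 rose (5 adjusted over the list alone), led by desat1, the stearoyl-CoA desaturase (2.30 ± 0.15, adjusted p = 2.3e-04, 34.1 against 6.16), AcCoAS, acetyl-CoA synthetase (1.37 ± 0.15), and Men, malic enzyme (1.17 ± 0.15). Of 8 triglyceride storage genes 6 rose (7 adjusted over the list alone), with Gpdh, glycerol-3-phosphate dehydrogenase, at 2.29 ± 0.10 (adjusted p = 7.9e-05) and the lipid droplet protein Lsd-1 at 1.48 ± 0.19. Glycolysis (9 of 12 rose, 10 adjusted over the list alone; Pgi 1.47 ± 0.10, Eno 1.33 ± 0.11) and glycogen, trehalose and gluconeogenesis (10 of 11 rose, 10 adjusted over the list alone; Tps1, trehalose-6-phosphate synthase, 1.45 ± 0.18) moved the same way. So did lipases and fatty acid oxidation (11 of 13 rose, 11 adjusted over the list alone; CG4389, the Mtpalpha gene, 0.87 ± 0.15) and endoplasmic reticulum chaperones (10 of 13 rose, 10 adjusted over the list alone; Gp93 1.70 ± 0.16). Sugarbabe, a zinc-finger factor induced by sugar, rose by 1.27 ± 0.25, and CG14375, which encodes the nutrient-responsive hormone CCHa2, by 1.53 ± 0.13.

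Some storage proteins and Toll-pathway peptides of the cg females were also higher at 0.7 M. Lsp1gamma, a larval hexamerin, went from 237 to 1740 (2.97 ± 0.38, adjusted p = 0.0016) and Lsp1beta from 561 to 1840 (1.73 ± 0.16), with 5 of 9 storage and secretory genes up (5 adjusted over the list alone). Of 9 Toll-pathway peptide genes 7 rose (7 adjusted over the list alone), among them CG15065, listed at 0 in all control libraries and at 8.67 on average on high sugar, IM2 (2.96 ± 0.73) and IM3 (2.82 ± 0.65). Of 14 antimicrobial peptides 2 rose and 1 fell (1 and 1 adjusted over the list alone; DptB 2.89 ± 0.85, dro5 -2.83 ± 0.35). The largest rises outside these lists were CG31775 and CG42586, neighbouring genes (3.8 ± 0.13 each, adjusted p = 1.3e-05), and CG3348 (3.18 ± 0.20). The results of CG31775 and CG42586 were the same, so they are not separate observations. The largest falls were Sgs7, a salivary glue protein (-5.61 ± 1.04, adjusted p = 0.0071, 1.33 against 191), CG7606 (listed at 0 on high sugar, 31.7 in controls), CG7587 (-4.24) and the metallothionein MtnA (-3.77 ± 0.11).

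Markers of other cells fell in the same cg female libraries, so the rises of fat genes there cannot be told apart from a larger share of fat body. Of 8 hemocyte markers 6 fell (6 adjusted over the list alone), with the prophenoloxidase gene CG8193 (PPO2) at 0 in all 0.7 M libraries and at 3.94 in controls and Hml at 0.0105 against 2.16. Of 7 gut markers 2 fell (4 adjusted over the list alone), the midgut proteases Jon65Aiv (-3.50 ± 0.82) and Jon65Aiii (-2.54 ± 0.71), and of 6 salivary gland markers 2 fell (6 adjusted over the list alone). With a preset correlation the set test ranked glycolysis, triglyceride storage and endoplasmic reticulum chaperones above other genes and hemocyte markers below them, and with an estimated one none. Glycolysis had adjusted p = 4.4e-04 and then adjusted p = 0.44 with an estimated correlation, triglyceride storage 0.0039 and 0.44, endoplasmic reticulum chaperones 4.4e-04 and 0.44, and hemocyte markers 1.2e-04 and 0.44. In all, 847 of 2131 genes tested changed at 0.7 M (585 higher, 262 lower), 263 of them by more than 2-fold. The count was 527 without library 2 of the 0.15 M group and 314 with the libraries' gut marker level as a covariate, and with the trend on transcript length removed the split was 418 higher and 437 lower. With no filter on low values it was 621 higher and 769 lower, so most calls being rises depends on these choices.

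In r4 w1118 females the 4 diets gave a dose series. Among genes of fatty acid synthesis, each diet tested against 0.15 M, desat1 averaged 5.17 at 0.15 M, 13.3 at 0.3 M (1.28 ± 0.29, adjusted p = 0.033), 20.2 at 0.7 M (1.86 ± 0.29, adjusted p = 0.0027) and 30.9 at 1.0 M (2.43 ± 0.29, adjusted p = 2.5e-04). Of the 7 genes of the list 2 rose at 0.3 M (3 adjusted over the list alone), 5 at 0.7 M (5 adjusted over the list alone) and 5 at 1.0 M (5 adjusted over the list alone), where Men reached 2.34 ± 0.26 and AcCoAS 2.19 ± 0.23. The set test at 1.0 M gave adjusted p = 7.3e-04, and adjusted p = 0.53 with an estimated correlation. Gpdh averaged 1.05, 2.96, 7 and 15.2 over the 4 diets (2.95 ± 0.23 at 1.0 M, adjusted p = 2.9e-05). CG3348 was among the largest rises at every step (2.08 ± 0.27, 3.72 ± 0.27 and 4.23 ± 0.27), and over the series by 4.62 per 1 M of sucrose, followed by Cyp4e3, a cytochrome P450 (4.60 ± 0.31), CG15068 (4.58) and the stress-induced humoral factor TotC (4.28 ± 0.87). The storage protein transcript Lsp1alpha fell along the series (-4.95 ± 0.63 per 1 M, adjusted p = 3.8e-04, 556 at 0.15 M and 38.7 at 1.0 M), in the direction opposite to that in cg females at 0.7 M, where it rose by 0.75 ± 0.20. The difference between the experiments was not tested.

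The nuclear genes of the respiratory chain were higher in r4 w1118 females at 1.0 M than at 0.15 M. There 23 of 28 rose (26 adjusted over the list alone), with a median change of 0.75, led by CG3731, the UQCR-C1 core subunit of complex III (1.21 ± 0.14, adjusted p = 2.2e-04), the cytochrome c gene Cyt-c-p (1.18 ± 0.16) and CG4692, an ATP synthase subunit (1.11 ± 0.16). At 0.3 M 4 of 28 rose (16 adjusted over the list alone) and at 0.7 M 8 of 28 (12 adjusted over the list alone), with medians of 0.47 and 0.42. The set test gave adjusted p = 6.8e-11 at 1.0 M, and adjusted p = 0.35 with an estimated correlation. Ribosomal protein genes were higher at 0.3 M in 6 of 79 cases (37 adjusted over the list alone, 0 after removal of the length trend, by limma), at 0.7 M in 13 (13 adjusted over the list alone), and at 1.0 M in 3 (0 adjusted over the list alone). Of 8 gut markers 4 fell at 0.3 M (5 adjusted over the list alone), 5 at 0.7 M (5) and 5 at 1.0 M (5). Jon65Aiv stood at 49.2 on the control diet, 13.7 at 0.3 M, 0.567 at 0.7 M (-4.89 ± 0.45) and 0.805 at 1.0 M (-4.69 ± 0.45). The gut list had adjusted p = 3.6e-09 at 0.7 M, and adjusted p = 0.37 with an estimated correlation.

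Of 2177 genes tested in r4 w1118 females, 168 changed at 0.3 M (138 higher, 30 lower), 311 at 0.7 M (247 higher, 64 lower) and 375 at 1.0 M (274 higher, 101 lower), and 381 followed the dose as a linear trend (262 higher, 119 lower). With the gut marker level as a covariate, limma called 1, 0, 0 and 1 genes, with 139, 111, 159 and 167 at an unadjusted p under 0.05; the gut markers themselves moved with the diet, so the covariate and the diet share most of their variation. With the length trend removed the splits were 48 higher and 29 lower at 0.3 M, 143 and 122 at 0.7 M, 216 and 141 at 1.0 M, and 229 and 163 for the trend. With no filter on low values lower genes outnumbered higher ones: 154 higher and 341 lower, 274 and 553, 347 and 507, and 341 and 421 in the same order. The 0.3 M count was 46 or 23 without library 1 or 3 of the 0.15 M group and 422, 34 or 25 without library 1, 2 or 3 of the 0.3 M group. The 0.7 M count was 190, 203 or 182 without library 1, 2 or 3 of the 0.15 M group and 113 or 163 without library 2 or 3 of the 0.7 M group. The 1.0 M count was 216 or 218 without library 1 of the 0.15 M or 1.0 M group, and the trend count 246 without library 1 of the 1.0 M group.

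In r4 60100 female controls on 0.7 M sucrose, CG15067 (BomBc2), a Toll-induced peptide gene, rose from 1.35 to 39.3 (4.13 ± 0.54, adjusted p = 5.4e-06, n = 4 and 4) and sad, an enzyme of ecdysteroid synthesis, from 2.95 to 33.4 (3.26 ± 0.26, adjusted p = 1.2e-09). CG14265 and CG13947 were listed at 0 in all control libraries and averaged 8.37 and 7.78 on high sugar, and CG3348 rose by 2.77 ± 0.34. Fatty acid synthesis rose in 5 of 9 genes and fell in 1, with Pgd, an NADPH-forming enzyme of the pentose phosphate pathway, at 1.31 ± 0.29, Men at 1.09 ± 0.22 and desat1 at 1.01 ± 0.19. Proteasome subunits rose in 14 of 26 cases (18 adjusted over the list alone; Prosalpha1 0.68 ± 0.14, Prosbeta3 0.67 ± 0.22), with a set test of adjusted p = 0.0047, and adjusted p = 0.73 with an estimated correlation. Storage and secretory genes fell in 5 of 9 cases and rose in 1 (Lsp1alpha -1.29 ± 0.24, 438 against 1010; Tsf1, transferrin, 1.05 ± 0.26), but after rescaling by the median ratio 2 fell. The largest falls were PGRP-SB2, listed at 0 on high sugar and at 6.02 in controls, ImpE2, an ecdysone-inducible gene (-1.82 ± 0.28), and MtnA (-1.42). Stat92E fell as well (-0.87 ± 0.19, adjusted p = 0.0016).

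Markers of muscle and gut rose in the r4 60100 controls on high sugar. They were 9 of 11 muscle genes (10 adjusted over the list alone; Mlc2, a myosin light chain, 2.0 ± 0.34) and 4 of 9 gut genes (4 adjusted over the list alone; Jon99Cii 2.06 ± 0.56, Jon99Ciii 2.05 ± 0.55). For muscle the set test gave adjusted p = 0.0047, and adjusted p = 0.73 with an estimated correlation. Of 5 hemocyte markers 0 rose and 1 fell (median -0.12), and of 6 salivary gland markers 1 rose (median 0.78). The falls of storage genes on high sugar thus cannot be told apart from a lower share of fat body, though hemocyte markers did not rise. In all, 784 of 2521 genes changed (471 higher, 313 lower), 117 by more than 2-fold. Rescaling by the median ratio moved the median change of all genes from 0.107 to 0.204 and the split to 677 higher and 208 lower. With no filter on low values the split was 690 higher and 1832 lower. The count was 514 or 513 without library 2 or 3 of the 0.7 M group, and 368 with the gut marker level as a covariate.

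The 3 female comparisons of 0.7 M with 0.15 M shared 72 genes changed in the same direction (61 higher, 11 lower) of 1686 tested in all, where independent lists of these sizes would share 10.2. Highest on average were CG3348 (3.18 ± 0.20 in cg, 3.72 ± 0.27 in r4 w1118 and 2.77 ± 0.34 in r4 60100 females), Cyp4e3 (1.97 ± 0.24, 3.49 ± 0.30 and 2.02 ± 0.22), and CG31775 and the neighbouring CG42586 (3.8 ± 0.13, 2.19 ± 0.24 and 1.35 ± 0.38 for each). The results of CG31775 and CG42586 were the same in all 3 comparisons, so they are not separate observations among the 72. The immune peptide IM3 followed (2.82 ± 0.65, 1.80 ± 0.39 and 1.5 ± 0.40). Next came Gpdh (2.29 ± 0.10, 1.97 ± 0.23 and 1.62 ± 0.24), Cyp4d1 (2.73 ± 0.22, 1.31 ± 0.29 and 1.33 ± 0.31) and desat1 (2.30 ± 0.15, 1.86 ± 0.29 and 1.01 ± 0.19). Lowest were the actin gene Act42A (-2.91 ± 0.30, -1.85 ± 0.17 and -1.35 ± 0.37), ImpE2 (-1.93 ± 0.19, -2.12 ± 0.36 and -1.82 ± 0.28) and CG32335 (-2.37 ± 0.16, -1.90 ± 0.18 and -1.20 ± 0.19). The shared count was 47, 35 or 42 without r4 w1118 library 3 at 0.15 M, 2 at 0.7 M or 3 at 0.7 M. With the length trend removed the shared genes split into 42 higher and 29 lower, and with no filter on low values into 60 higher and 94 lower. Across genes, which are not independent replicates, the changes correlated at 0.54 (cg with r4 w1118), 0.32 (cg with r4 60100) and 0.47 (r4 w1118 with r4 60100).

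**Figure D2:**
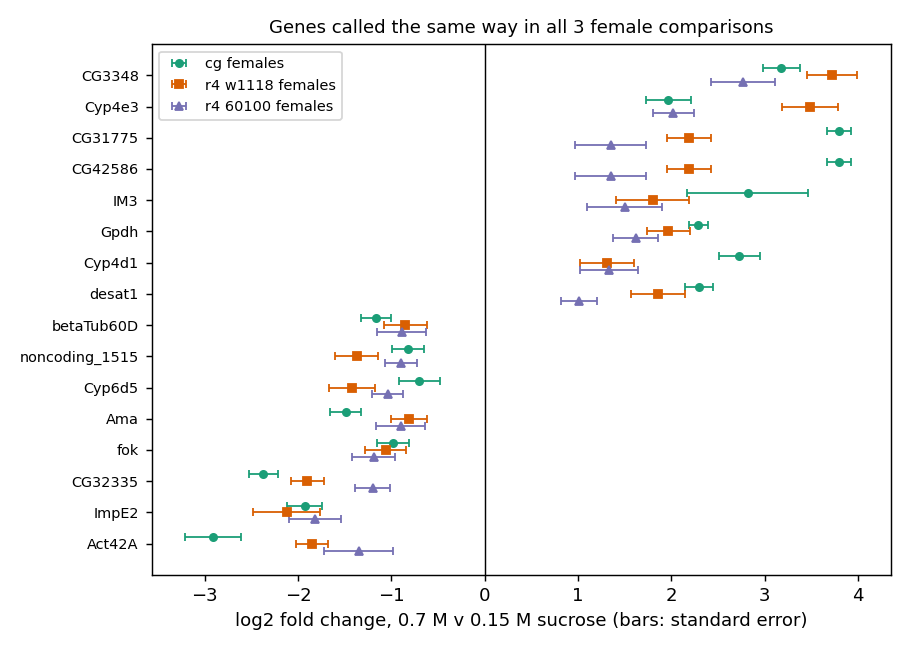
Log2 change ± SE at 0.7 M against 0.15 M sucrose (x axis) for the 8 highest and 8 lowest genes shared by the 3 female comparisons, with a point per experiment. CG3348 lay at 3.18, 3.72 and 2.77 and Act42A at -2.91, -1.85 and -1.35.

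In cg males, storage and amino acid genes were lower at 1.0 M sucrose than at 0.15 M. Of 10 storage and secretory genes 7 fell (8 adjusted over the list alone): Lsp1alpha went from 1330 to 82.1 (-4.09 ± 0.30, adjusted p = 1.1e-05, n = 3 and 3), Lsp1gamma from 2190 to 671 (-1.75 ± 0.24) and Lsp1beta from 1740 to 568 (-1.62 ± 0.24). Of 15 amino acid and one-carbon genes 9 fell and 1 rose, with Got2, aspartate aminotransferase, at -2.23 ± 0.24 and CG6188, glycine N-methyltransferase, at -2.05 ± 0.16. Glycolysis fell in 5 of 9 genes (6 adjusted over the list alone; Aldolase -1.17 ± 0.29), a direction opposite to that in the females at 0.7 M, which was not tested against it. Lower too were 6 of 10 immune signalling genes (6 adjusted over the list alone; PGRP-SD -1.16 ± 0.13) and 3 of 12 antimicrobial peptides (AttB -2.75 ± 0.54), and of 13 secreted factors 6 fell and 1 rose (Nplp2 -2.65 ± 0.36). The largest rises were Cyp4e3, from 0.294 to 35.8 (4.80 ± 0.21, adjusted p = 8.2e-07), and CG3348 (3.52 ± 0.31). The single genes desat1 (0.64 ± 0.21) and Gpdh (1.17 ± 0.29) rose, but their lists did not. Fatty acid synthesis had 1 rise and 1 fall among 7 genes (median 0.08) and triglyceride storage 1 and 1 among 8 (median -0.03). Of 15 lipase and oxidation genes 0 rose and 4 fell. Sperm genes of the testis list rose in 3 of 6 cases (4 adjusted over the list alone; dj 0.84 ± 0.25). Storage genes had a set test of adjusted p = 0.013, and adjusted p = 0.9 with an estimated correlation. Of 27 respiratory chain genes 1 rose and 4 fell (median -0.27), unlike the rise in r4 w1118 females at 1.0 M, and the experiments were not tested against each other. In all, 763 of 2698 genes changed (145 higher, 618 lower), 209 by more than 2-fold. The count was 495 without library 1 of the 0.15 M group, and without the length trend the split was 267 higher and 443 lower; ribosomal proteins, lower in 12 of 82 cases (0 adjusted over the list alone, by limma), then stood at 3 higher and 3 lower.

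Tfb1 RNAi in cg males addressed what RNAi against a TFIIH subunit does on each diet. A fall of Tfb1 itself was not shown at 1.0 M (-0.15 ± 0.09, adjusted p = 0.35 in limma with no filter; -0.31 ± 0.09 and 0.048 at 0.15 M). At 0.15 M the largest rises were Arc1, a Gag-like capsid protein, from 5.82 to 377 (5.79 ± 0.20, adjusted p = 3.5e-08, n = 3 and 3), CG10102 (5.38 ± 0.13), CG15347 (4.08), Obp49a (4.06) and Cyp6d2 (3.77). The p53 transcript, near 0 in controls (0.0717), averaged 2.04 (1.5 ± 0.13, adjusted p = 8.9e-06), and at 1.0 M 1.86 against 0.112 (1.36 ± 0.13, adjusted p = 3.2e-05). TotC rose by 3.03 ± 0.32 and TotA by 2.48 ± 0.15, with 3 of 5 JAK/STAT genes higher and 2 lower. Thor, the 4E-BP translation inhibitor and a known FOXO target, fell from 154 to 17.3 (-3.08 ± 0.12, adjusted p = 4.8e-08). The largest fall was CG6188, glycine N-methyltransferase (-3.72 ± 0.16). Fat genes fell. They were 6 of 7 of fatty acid synthesis (6 adjusted over the list alone; AcCoAS -1.39 ± 0.26), 5 of 8 of triglyceride storage (7 adjusted over the list alone; Lsd-1 -2.09 ± 0.18) and 10 of 15 lipase and oxidation genes (10 adjusted over the list alone; scu -1.77 ± 0.17). Of 82 ribosomal protein genes 55 fell (58 adjusted over the list alone; oho23B -1.41 ± 0.13), or 38 with the length trend removed. The set test for ribosomal proteins gave adjusted p = 3.9e-06, and adjusted p = 0.78 with an estimated correlation. Detoxification genes went both ways (6 of 24 rose, 13 fell; GstD3 2.56 ± 0.10, GstD1 -2.0 ± 0.17).

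At 1.0 M Arc1 (5.34 ± 0.20, 195 against 4.01) and CG10102 (4.59) again rose the most in Tfb1 RNAi, followed by CG8299 (4.19) and MtnA (3.68). Thor fell by 2.23 ± 0.12, 5 of 10 storage genes fell and 1 rose (Lsp1alpha -2.35 ± 0.30), and 5 of 27 respiratory chain genes rose (0 adjusted over the list alone, by limma; ox 2.38 ± 0.77). Triglyceride storage fell in Lsd-1 alone (-1.24 ± 0.18). In all, 976 of 2698 genes changed at 0.15 M (280 higher, 696 lower), 651 at 1.0 M (329 higher, 322 lower), and 227 differed between the diets (192 with the higher change at 1.0 M, 35 with the lower). Among these Men (1.34 ± 0.31), desat1 (1.32 ± 0.29) and the lipase gene Lip4 (1.27 ± 0.21) changed less negatively at 1.0 M. Tfb1 itself was at 73.4% of control there and at 57% at 0.15 M, so for these genes a weaker knockdown at 1.0 M stays open. The ribosomal list differed as a set (median 0.42, adjusted p = 7.5e-05, and adjusted p = 0.66 with an estimated correlation) with no member called by limma. The larval salivary markers ng1, ng2 and ng3 fell at 0.15 M (-1.27, -1.29 and -1.25) and rose at 1.0 M (1.40, 1.28 and 1.22), where 5 of the other 7 fell (Sgs1 -1.17 ± 0.19). With the length trend removed the splits were 404 higher and 527 lower at 0.15 M and 158 and 54 for the difference. The difference count was 147, 137 or 427 without Tfb1 RNAi library 1, 2 or 3 at 1.0 M, and 127 with the gut marker level as a covariate.

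**Figure D3:**
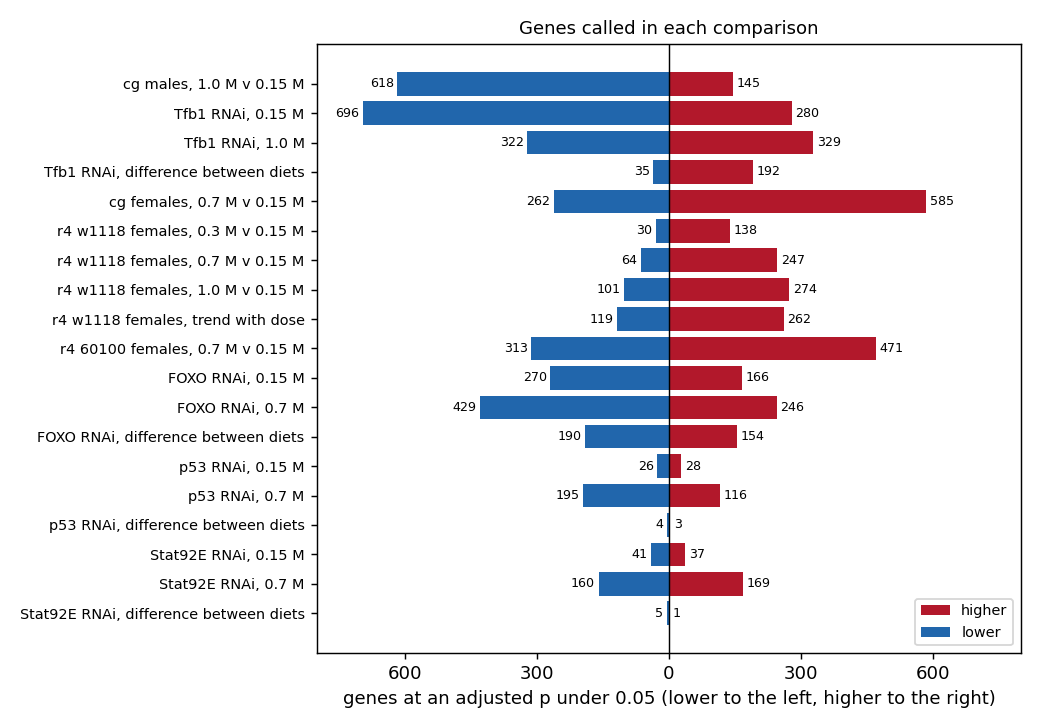
Number of genes called by limma at an adjusted p under 0.05 in each comparison (x axis), with bars to the right for higher and to the left for lower. The bars run from 1 higher and 5 lower for the Stat92E difference between diets to 280 higher and 696 lower for Tfb1 RNAi at 0.15 M.

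In FOXO RNAi of r4 60100 females, genes of storage and glucose output were lower than in controls. At 0.15 M 7 of 9 storage genes fell (7 adjusted over the list alone; Lsp1alpha -1.07 ± 0.24, Lsp1beta -0.99 ± 0.19, n = 4 and 4), or 4 after rescaling, and 5 of 11 glycogen, trehalose and gluconeogenesis genes fell (5 adjusted over the list alone). Among the latter Pepck, which commits to glucose synthesis, went from 117 to 39.9 (-1.51 ± 0.20, adjusted p = 8.3e-06). The insulin-like peptide gene Ilp6 (-1.03 ± 0.21) and Thor (-0.76 ± 0.23), both known FOXO targets, fell. The foxo transcript was lower still in Stat92E RNAi at this diet, so its level does not show that these falls follow from less foxo. Of 15 amino acid genes 7 fell and 1 rose (Nmdmc -1.07 ± 0.32). Of 9 antimicrobial peptides 3 fell (4 adjusted over the list alone; Dro -1.55 ± 0.33, AttA -1.31 ± 0.26). Gut markers rose in 4 of 9 cases (5 adjusted over the list alone; Jon65Aiv 2.97 ± 0.89) and salivary markers fell in 5 of 6 (5 adjusted over the list alone; Sgs7 -2.24 ± 0.46). The set test for storage gave adjusted p = 2.3e-04, and adjusted p = 0.29 with an estimated correlation.

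At 0.7 M the largest rises in FOXO RNAi were LysX, a lysozyme, from 1.27 to 86.1 (5.21 ± 0.31, adjusted p = 9.2e-13), CG1213, a sugar transporter-like gene (3.46 ± 0.09), the amidase PGRP-SC2 from 84.9 to 734 (3.10 ± 0.29, adjusted p = 4.4e-09) and TotC (3.06 ± 0.53). Immune signalling rose in 5 of 14 genes and fell in 3 (8 and 3 adjusted over the list alone), with a set test of adjusted p = 0.025, and adjusted p = 0.088 with an estimated correlation. Antimicrobial peptides fell in 3 of 9 (3 adjusted over the list alone), AttA the most. Storage fell in 6 of 9 genes (6 adjusted over the list alone; Fbp2 -1.37 ± 0.16) and amino acid metabolism in 9 of 15 (9 adjusted over the list alone; CG6188 -1.65 ± 0.38). ImpL2, an insulin-binding protein, rose by 1.29 ± 0.17, Zw, glucose-6-phosphate dehydrogenase, by 1.27 ± 0.16, and Aldh-III by 1.26 ± 0.11. Gut markers fell in 3 of 9 cases (3 adjusted over the list alone; Jon65Aiv -2.64 ± 0.89). Without FOXO RNAi library 2 at 0.7 M limma called 0 of the 9 gut genes (3 at an unadjusted p under 0.05), and 5 amino acid genes fell. In all, 436 of 2521 genes changed at 0.15 M (166 higher, 270 lower), 675 at 0.7 M (246 higher, 429 lower) and 344 differed between the diets (154 higher, 190 lower); Pepck (1.60 ± 0.28) and ImpL2 (1.49 ± 0.24) were among the last. Rescaling gave 229 higher and 193 lower, 300 and 279, and 158 and 123, and removal of the length trend 355 and 291 at 0.7 M and 193 and 84 for the difference. With no filter on low values the splits were 671 higher and 529 lower at 0.7 M and 460 and 238 for the difference. The 0.15 M count was 288 without FOXO RNAi library 4. The difference count was 217, 618 or 224 without FOXO RNAi library 1, 2 or 3 at 0.15 M, 546 without library 4 at 0.7 M, 224 or 541 without control library 2 or 4 at 0.7 M, and 85 with the gut marker level as a covariate.

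In p53 RNAi at 0.15 M (3 libraries against 4) the immune peptides were higher. Of 9 antimicrobial peptides 6 rose (8 adjusted over the list alone): DptB, a diptericin, went from 1.07 to 9.6 (2.36 ± 0.26, adjusted p = 1.7e-06), Drs, drosomycin, from 30 to 121 (1.90 ± 0.36, adjusted p = 0.0036) and Mtk, metchnikowin, from 3.14 to 12.6 (1.74 ± 0.40). This list kept its call with an estimated correlation (adjusted p = 1.3e-12, and adjusted p = 0.0011 with an estimated correlation). Of 8 Toll-induced peptides 5 rose (8 adjusted over the list alone; IM14 2.33 ± 0.57), with adjusted p = 6.9e-09, and adjusted p = 0.12 with an estimated correlation. Of 14 immune signalling genes 2 rose (4 adjusted over the list alone; PGRP-SC1a 1.31 ± 0.20), with adjusted p = 3.8e-04, and adjusted p = 0.0096 with an estimated correlation. The hemocyte genes CG8193 (0.86 ± 0.21) and proPO-A1 (0.73 ± 0.19) rose in the same libraries, as did 1 of 9 gut markers (5 adjusted over the list alone; alphaTry 1.88 ± 0.45). The falls were smaller, led by CG7966 (-0.85), Cyp4e2 (-0.77 ± 0.16) and Cyp6d5 (-0.76).

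At 0.7 M storage and fat genes were lower in p53 RNAi than in controls. Of 9 storage genes 7 fell (8 adjusted over the list alone), with Lsp1alpha at 98.7 against 438 (-2.07 ± 0.24, adjusted p = 3.7e-06), Lsp1gamma at 301 against 858 (-1.45 ± 0.20) and Tsf1 at -1.22 ± 0.26. The set test gave adjusted p = 6.2e-08, and adjusted p = 0.029 with an estimated correlation. Fatty acid synthesis fell in 3 of 9 genes (4 adjusted over the list alone; CG3523, fatty acid synthase, -1.01 ± 0.25), triglyceride storage in 4 of 10 (5 adjusted over the list alone; Gpdh -1.09 ± 0.24) and detoxification in 9 of 18 (10 adjusted over the list alone; Cyp28d1 -0.99 ± 0.16). Of 6 salivary gland markers 1 fell (5 adjusted over the list alone; Sgs5 -1.86 ± 0.59), with a median of -1.08. The largest rises were CG10814, from 0.223 to 32.1 (4.47 ± 0.30, adjusted p = 7.0e-11), LysX (2.50) and CaBP1, a protein disulfide isomerase (1.83 ± 0.24). DptB rose by 1.33 ± 0.24 while Drs fell by 1.18 ± 0.33, so that 4 of 9 antimicrobial peptides rose and 1 fell. In all, 54 of 2521 genes changed at 0.15 M (28 higher, 26 lower), 311 at 0.7 M (116 higher, 195 lower) and 7 differed between the diets, CG10814 the most (4.39 ± 0.44). Rescaling gave 29 higher and 12 lower at 0.15 M, and removal of the length trend 184 and 190 at 0.7 M. The 0.15 M count was 24 or 33 without control library 1 or 3 and 14 or 12 without p53 RNAi library 1 or 3, and 33 with the gut marker level as a covariate. The 0.7 M count was 122, 612 or 117 without control library 1, 2 or 4 and 198, 151 or 189 without p53 RNAi library 1, 2 or 4. The difference count was 13 or 4 without control library 2 or 4 at 0.15 M, 3, 13 or 4 without control library 1, 2 or 3 at 0.7 M. It was 3, 15 or 3 without p53 RNAi library 1, 2 or 3 at 0.15 M, 3 without p53 RNAi library 2 or 4 at 0.7 M, and 4 with the covariate.

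In Stat92E RNAi at 0.7 M the genes of the JAK/STAT list, which includes Stat92E itself, were lower than in controls. All 5 measured genes of the list fell (5 adjusted over the list alone): TotC from 11.3 to 0.222 (-3.29 ± 0.53, adjusted p = 4.3e-04, n = 4 and 4). Next were TotA from 67.3 to 21.8 (-1.60 ± 0.37, adjusted p = 0.0076), TepII, a thioester-containing immune protein (-0.85 ± 0.27), and Stat92E itself (-0.67 ± 0.19). The set test gave adjusted p = 8.0e-05, and adjusted p = 0.15 with an estimated correlation. In p53 RNAi at 0.7 M, with the same controls, 2 of the 5 fell (median -0.43). Storage fell in 5 of 9 genes (5 adjusted over the list alone; Lsp1alpha -1.52 ± 0.24, Lsp1gamma -1.3 ± 0.20), fatty acid synthesis in 3 of 9 (5 adjusted over the list alone; CG3523 -1.18 ± 0.25) and triglyceride storage in 3 of 10 (3 adjusted over the list alone; Gpdh -1.10 ± 0.24). Of 6 salivary gland markers 1 fell (2 adjusted over the list alone; Sgs5 -1.86 ± 0.59), with a median of -0.99. Proteasome subunits rose in 15 of 26 cases (16 adjusted over the list alone; Pros29 0.49 ± 0.11, Prosbeta7 0.49 ± 0.13), with adjusted p = 3.9e-06, and adjusted p = 0.37 with an estimated correlation. The largest rises after white (1.99 ± 0.14) were SC35, a splicing factor (1.3), CG4789 (1.19) and CG11899 (1.05).

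At 0.15 M Stat92E alone of the 5 JAK/STAT genes passed in Stat92E RNAi (-1.31 ± 0.19, adjusted p = 3.1e-04; 2 adjusted over the list alone). The difference between diets was called in 0 of the 5 by limma. The neuropeptide-like gene Nplp2 rose from 104 to 243 (1.22 ± 0.30, adjusted p = 0.027). Among ribosomal protein genes 3 of 79 rose (26 adjusted over the list alone; RpL29 0.78 ± 0.20), with adjusted p = 7.3e-11, adjusted p = 0.56 with an estimated correlation, and 0 genes called by limma once the length trend was removed. In all, 78 of 2521 genes changed at 0.15 M (37 higher, 41 lower), 329 at 0.7 M (169 higher, 160 lower) and 6 differed between the diets (1 higher, 5 lower). Rescaling gave 47 higher and 25 lower at 0.15 M and removal of the length trend 6 and 19. With no filter on low values 0.15 M gave more genes (94 higher, 493 lower) than 0.7 M (177 higher, 181 lower). The 0.15 M count was 10, 22 or 21 without Stat92E RNAi library 1, 3 or 4, 18, 46, 42 or 25 without control library 1, 2, 3 or 4, and 17 with the gut marker level as a covariate. The 0.7 M count was 173 or 183 without Stat92E RNAi library 1 or 3 and 125, 567 or 124 without control library 1, 2 or 4. The difference count was 10 or 34 without Stat92E RNAi library 4 at 0.15 M or at 0.7 M, 14 without control library 2 at 0.15 M, and 11 or 12 without control library 2 or 4 at 0.7 M.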

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

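Every test of an explanation in this part was chosen after the result was seen; the differences between diets were planned. Single libraries were compared within the 7 groups of 4 libraries on 10 measures each, and 8 of the 70 tests put a library farther from the others than the limit of Dixon's test at 0.05. Chance flags about 1 in 20, or 3.5 of 70. All 8 fell on library 2, by column order, of a r4 60100 female group. FOXO RNAi library 2 at 0.15 M had 8939 genes above 0 (8401 to 8429 in the others of its group), 11.64% of its total in its top gene (15.11 to 15.64%) and 2.14 scaled FPKM of Stat92E (0.854 to 0.936). Control library 2 at 0.15 M had 13.53% of its total in its top gene (16.66 to 17.13%) and an estimated depth of 1.14 M fragments (0.901 to 0.926 M). FOXO RNAi library 2 at 0.7 M had 1.73 of Stat92E (0.595 to 0.701) and 21.1 of Dcr-2 (3.88 to 6.72). Stat92E RNAi library 2 at 0.15 M had 23.2 of Dcr-2 (10.9 to 12.6).

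The effect of Tfb1 RNAi differed between 0.15 M and 1.0 M sucrose in 227 genes by the test of the difference. CG8299 changed by 4.09 more at 1.0 M (0.09 at 0.15 M, 4.19 at 1.0 M), CG6912 by 3.23 (-2.35 and 0.88) and CG10962 by 2.94 (-3.28 and -0.34). In the other direction the differences were -2.60 for CG6296 (-0.33 and -2.93) and -2.59 for the drosomycin-like gene dro5 (0.26 and -2.33). Of 100 splits of the libraries 8 called at least as many genes, the highest of the others 1069, so chance was not excluded for the count. Splits that exchange the RNAi and control labels at 1 of the diets turn the difference into a sum. The split with 1069 was of this kind (3 controls exchanged at 0.15 M, 0 at 1.0 M). Its count points to a structure of the samples, the RNAi effect at both diets. Tfb1 itself stood at 57% of control at 0.15 M and 73.4% at 1.0 M. For changes that were smaller at 1.0 M, a weaker knockdown there cannot be told apart from an effect of diet. The other targeted transcripts also differed in percent of control at 0.15 M and 0.7 M (foxo 56.9% and 65%, p53 71.6% and 62.2%, Stat92E 16.5% and 23.8%). Whether knockdown differed between diets was not tested.

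The effect of FOXO RNAi differed between 0.15 M and 0.7 M in 344 genes. Higher at 0.7 M were LysX by 3.92 (1.29 at 0.15 M, 5.21 at 0.7 M), CG1213 by 3.06 (0.40 and 3.46) and CG7298 by 2.98 (-0.04 and 2.94). Lower were the gut proteases Jon65Aiv by -5.61 (2.97 and -2.64) and Jon25Bi by -4.49 (2.28 and -2.21), and CG14302 by -4.70 (2.84 and -1.85). Of 100 splits 3 called as many, the real one included, with 434 as the highest other, a share under 0.05. The split with 434 exchanged 1 control library at 0.15 M and 4 at 0.7 M. Such splits carry the RNAi effect itself, so the share does not settle whether chance gives the difference.

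The effect of p53 RNAi differed between diets in 7 genes. Higher at 0.7 M were CG10814 by 4.39 (0.08 at 0.15 M, 4.47 at 0.7 M), LysX by 2.07 (0.43 and 2.50) and CaBP1 by 1.80 (0.03 and 1.83), and lower were Drs by -3.08 (1.90 and -1.18), CG8160 by -2.14 (1.75 and -0.39) and CG3868 by -1.42 (0.64 and -0.78). Of 100 splits 10 called as many, the highest of the others 264, so chance was not excluded. The effect of Stat92E RNAi differed in 6 genes, with CG17919 higher at 0.7 M by 0.91 (0.06 and 0.97) and CG3868 lower by -1.34 (0.61 and -0.73), CG32068 by -1.12 (0.38 and -0.74) and CG16799 by -0.87 (0.27 and -0.60). Of 100 splits 5 called as many, the highest of the others 96, so chance was not excluded. The highest split of p53 exchanged 3 control libraries at 0.15 M and 1 at 0.7 M, and that of Stat92E 1 and 3. These come near an exchange at 1 diet, and the other splits were not examined.

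Gut protease transcripts moved with diet in opposite directions, with list medians of -2.02 at 0.7 M in r4 w1118 females and 1.32 in r4 60100 females, and in FOXO RNAi Jon65Aiv and Jon25Bi rose at 0.15 M and fell at 0.7 M, where without FOXO RNAi library 2 the falls missed the threshold (adjusted p = 0.11 and 0.12). A lower share of fat body in some libraries, which would raise the markers of all other cells alike, is argued against in r4 w1118 females: the gut median differed from the muscle median by 2.18, with muscle at 0.16 and hemocytes at 0.03. In r4 60100 females muscle (0.95) and salivary gland (0.78) moved with gut while hemocytes stood at -0.12. In cg females at 0.7 M the medians of salivary gland (-2.96), gut (-1.39) and hemocyte (-1.21) markers all fell. A share of fat body that differs between the diets thus stays open in cg females and in r4 60100 females. Gut tissue carried over into some libraries is a candidate explanation. In r4 w1118 females the 8 gut markers varied together within groups at a mean correlation of 0.51, which none of 1000 random lists reached (the highest also rounds to 0.51). In r4 60100 females it was 0.33 and random lists reached 0.4. A response of gut-type genes in the fat body to diet was not tested and stays open.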

How the results depend on the processing

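Alternatives on the length trend, the gut covariate, the block in males and r4 60100 females, libraries set apart, and each library left out for the shared and targeted genes were chosen after seeing the data; the cause of the moves below was not tested unless stated. Rescaling by the median ratio kept every gene count within 1.5 times the value reported, and so did the replicate block in cg females (734), r4 w1118 females (149, 298, 353 and trend 376; shared 67) and cg males (714 for diet, 954, 611 and difference 185 for Tfb1). After removal of group means, libraries with the same number had correlations of -0.07 to 0.09 in cg females, -0.20 to 0.37 in r4 w1118 females (6 of 18 over 0.1) and -0.24 to 0.4 in cg males (7 of 18). Libraries with other numbers had -0.18 to 0.18 (3 of 6), -0.3 to 0.22 (8 of 36) and -0.58 to 0.43 (12 of 36) in the same order. The main fits used the number as a name only, and a weak batch shared by number stays open. In r4 60100 females most columns carry no number. A replicate block by column order gave 11 for the Stat92E difference and kept every other count within 1.5 times. Libraries at the same position had correlations of -0.56 to 0.58, with a mean of 0.05 and 42 of 105 over 0.1. At other positions the mean was -0.01, with 79 of 315 over 0.1. All 8 flags of the tests of single libraries also fell on library 2. A batch shared by column position thus stays open, and the r4 60100 results above do not account for it. The labels divide the r4 60100 samples of every group between replicate sets. A term for the set was not run because columns could not be matched to titles, so every r4 60100 result ignores the sets.

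With no filter on low values more genes are tested. The counts were then 1390 in cg females, 2522 in r4 60100 females, 495, 827, 854 and trend 762 in r4 w1118 females, and 154 shared. For RNAi they were 858, 1200 and 698 for FOXO at 0.15 M, at 0.7 M and their difference, 108 for p53 RNAi at 0.15 M, 587 for Stat92E RNAi at 0.15 M and 14 for its difference. A pseudocount of 0.1 gave 4 for the p53 difference. One fit over all libraries gave 12 for the p53 difference, 178 for Stat92E RNAi at 0.15 M and 17 for its difference, 391, 571, 569 and trend 599 in r4 w1118 females and 561 for the Tfb1 difference. A relaxed threshold gave 175 shared genes, and the estimated correlation kept 4 list calls of 119. Without the length trend Stat92E RNAi at 0.15 M gave 25 and 0.3 M in r4 w1118 females 77. The gut covariate gave 314 in cg females, 368 in r4 60100 females, 85 for the FOXO difference, 33 for p53 RNAi at 0.15 M and 4 for its difference, 17 for Stat92E RNAi at 0.15 M, and 127 for the Tfb1 difference. It gave 1, 0, 0 and trend 1 in r4 w1118 females (limma; 139, 111, 159 and 167 at an unadjusted p under 0.05), where the gut level itself fell with diet. FOXO RNAi library 2 at 0.7 M stood apart (mean correlation 0.933); without it FOXO RNAi at 0.7 M gave 516 genes and the difference 246.

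Leaving out each library in turn gave 527 to 741 genes in cg females, 513 to 1002 in r4 60100 females and 495 to 776 in males. It gave 23 to 422, 113 to 231, 216 to 323 and trend 246 to 372 in r4 w1118 females, and 35 to 82 shared genes. For RNAi at the low diet, at the high diet and their difference it gave 288 to 600, 516 to 757 and 217 to 618 for FOXO, 12 to 63, 117 to 612 and 3 to 15 for p53, 10 to 90, 124 to 567 and 5 to 34 for Stat92E and 783 to 873, 474 to 758 and 137 to 427 for Tfb1. Targeted genes ranged from -0.38 to -0.22 and -0.19 to -0.12 (Tfb1), -0.29 to -0.22 and -0.16 to -0.05 (foxo), -0.06 to -0.03 and -0.13 to -0.08 (p53) and -1.43 to -1.13 and -0.74 to -0.56 (Stat92E) at the low and high diet. Dcr-2 ranged from -1.87 to -1.73 and -1.41 to -1.13 in Tfb1, -1.45 to -0.89 and -0.58 to 0.20 in FOXO, -1.03 to -0.62 and -1.40 to -0.78 in p53 and -0.85 to -0.39 and -1.02 to -0.40 in Stat92E RNAi. The change of p53 at 0.7 M, -0.10 after rescaling, then missed 0.05. It missed 0.05 too with any of its 4 RNAi libraries left out, though the groups did not overlap and the smallest possible value stayed at 0.029. CG9485 in p53 RNAi at 0.7 M turned from -0.24 to 0.05 without the length trend. Of the calls of named genes, those kept and lost were 1005 and 73 after rescaling, 1017 and 61 with a pseudocount of 0.1, 884 and 194 with no filter, 987 and 91 in one fit, 909 and 156 without the length trend and 570 and 508 with the gut covariate. Depth limits genes near 1 scaled FPKM, where a value rests on 2.22 to 25.2 fragments per kilobase.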

Other observations

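Of the tests of explanations in this part, the one on transcript length was set before its value was computed, though after the pattern was seen, and all others were chosen only after the result was seen. Overlap was counted between the 3 knockdowns in r4 60100 females. At 0.7 M p53 and Stat92E RNAi shared 54 higher and 96 lower genes of 2521, where 7.78 and 12.4 are given by independent lists, and 1 gene moved in opposite directions. FOXO and p53 RNAi shared 26 higher and 86 lower (11.3 and 33.2), with 14 opposite, and FOXO and Stat92E RNAi 17 and 57 (16.5 and 27.2), with 27 opposite. All 3 used the same 4 control libraries, which alone give correlated changes across genes (about 0.5 in simulated values with no change). The real correlations at 0.7 M were 0.65 for p53 with Stat92E, 0.26 for FOXO with p53 and 0.09 for FOXO with Stat92E. With 2 of the control libraries for 1 knockdown of a pair and the other 2 for the other, the genes sharing a direction numbered 9 to 23 for p53 and Stat92E, 16 to 68 for FOXO and p53 and 4 to 45 for FOXO and Stat92E. At 0.7 M 54 genes changed in the same direction in all 3 knockdowns (8 higher, 46 lower), and 1 to 8 when the 4 controls were dealt out 2, 1 and 1. That fit has fewer controls and assumes that a lone library varies like the other groups. With the controls split between a pair, correlations at 0.7 M were 0.27 to 0.51 for p53 with Stat92E. They were -0.06 to 0.28 for FOXO with p53 and -0.15 to 0.08 for FOXO with Stat92E. In 50 simulations with no change 0 genes were called in both of a pair, but simulated genes vary independently within a library. The white gene, used to mark transgenes, was among the 8 higher in all 3 (2.65 in FOXO, 1.29 in p53 and 1.99 in Stat92E RNAi). The shared genes thus need not all be responses to the knockdowns. How much of the overlap comes from the shared controls, or from differences of the RNAi stocks from the control stock, stays open. Among the 46 genes lower in all 3 were the storage proteins Lsp1alpha (-0.91 in FOXO, -2.07 in p53 and -1.52 in Stat92E RNAi), Lsp1gamma (-1.14, -1.45 and -1.3) and Lsp1beta (-0.85, -0.89 and -0.89), pr, an enzyme of pteridine synthesis (-1.10, -0.95 and -1.47), and Cyp28d1 (-1.11, -0.99 and -0.74). At 0.15 M 3 genes changed the same way in all 3, white higher and kal-1 and CG4484 lower. The correlations there were 0.48 for p53 with Stat92E RNAi, with 1 higher and 3 lower genes shared, and 0.47 for FOXO with p53. For FOXO with Stat92E it was 0.57, with 10 higher and 28 lower genes shared.

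Single genes of secreted signals passed in several comparisons, and the set test of their list passed in none (lowest adjusted p 0.097). At 0.7 M 6 of 13 rose in cg females (6 adjusted over the list alone), 1 of 14 in r4 w1118 females (1), and 2 rose and 2 fell in r4 60100 females (2 and 2). In FOXO RNAi at 0.7 M 1 of 14 rose and 4 fell (1 and 5). In cg males 1 of 13 rose and 6 fell at 1.0 M (1 and 7), and 1 rose and 5 fell in Tfb1 RNAi at 0.15 M (1 and 6). CG14375, the CCHa2 gene, rose at 0.7 M in r4 w1118 females (1.87 ± 0.18, adjusted p = 1.4e-04) and in r4 60100 females (0.81 ± 0.13, adjusted p = 1.0e-04), and fell in FOXO RNAi at 0.7 M (-0.77 ± 0.13, adjusted p = 7.8e-05). There it followed ImpL2 (1.29 ± 0.17), Obp99b, an odorant-binding protein (-1.19 ± 0.21), and the growth-blocking peptide gene CG11395 (-1.0 ± 0.14). In r4 60100 controls another growth-blocking peptide gene, CG15917, fell at 0.7 M (-0.99 ± 0.25) and Ilp6, an insulin-like peptide, by 0.78 ± 0.21. In Tfb1 RNAi at 0.15 M CG8317, the limostatin gene (-1.76 ± 0.13), and CG11395 (-1.25 ± 0.12) fell. Nmdmc, an enzyme of folate metabolism, fell at 0.7 M in r4 60100 controls (-1.5 ± 0.32, adjusted p = 0.0012). The heat shock list fell there in 3 of 8 genes (3 adjusted over the list alone; Hsp23 -1.10 ± 0.35) with adjusted p = 0.012, and adjusted p = 0.73 with an estimated correlation. Mitochondrial ribosomal proteins rose in FOXO RNAi at 0.15 M in 5 of 28 genes (7 adjusted over the list alone; mRpL49 0.44 ± 0.12) with adjusted p = 0.0012, and adjusted p = 0.45 with an estimated correlation.

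The respiratory chain genes, higher at 1.0 M in r4 w1118 females with a median of 0.75, are shorter than other genes (median transcript 934 against 1564.5 bases). Transcript length is argued against as the whole cause: the list exceeded genes matched on length by 0.64, and the highest median of 10000 random lists so matched was 0.63. Scaling between libraries is argued against, since the median was 0.76 after rescaling. Less gut tissue at 1.0 M is argued against as the whole cause. With the gut marker level as a covariate the list's mean per library was still 0.77 ± 0.23 higher than at 0.15 M, though that level and the diet share most of their variation. From 0.7 M to 1.0 M the gut mean did not go down (0.09 ± 0.15), and the list's mean was 0.3 ± 0.09 higher (exact permutation p = 0.1, the smallest that 3 against 3 can give). In that step 26 of 28 members were higher and 0 were called by limma (12 genes called and 386 at an unadjusted p under 0.05). As part of the cause less gut tissue stays open, since within groups the list moved by -0.03 ± 0.09 per unit of gut level. A response to diet may account for the pattern and was not tested apart from the gut. In cg males, the other experiment with 1.0 M, the list's median was -0.27.

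The p53 transcript, 1.5 ± 0.13 higher in Tfb1 RNAi at 0.15 M and 1.36 ± 0.13 at 1.0 M, was weighed against scaling and RNA from other cells. Scaling between libraries is argued against, with a change of 1.48 after rescaling at 0.15 M and 1.33 at 1.0 M. RNA from salivary gland, gut, muscle or testis is argued against, since none of their lists was higher at both diets: the highest lower median was -0.35, for testis (0.14 at 0.15 M). RNA from other cells stays open. The lists of hemocytes, Malpighian tubules, neurons, trachea and epidermis, imaginal discs and ovary had at most 4 members past the filter, and with no filter their highest lower median was 0.08, for hemocytes, near the floor of detection. A p53 response is a hypothesis, tested on 15 detected genes of the p53 and DNA damage list other than p53. Their median of 0.25 at 0.15 M stood at percentile 100 of random lists matched on size and level. Without the filter Ku80 (0.87 ± 0.10, adjusted p = 2.4e-04), rad50 (0.78 ± 0.06), Irbp (0.65 ± 0.08), mre11 (0.60 ± 0.08) and Gadd45 (0.34 ± 0.07, adjusted p = 0.011) rose. These 5 averaged at most 1.05 scaled FPKM in either group, so few fragments carry them, and less Tfb1, part of the repair factor TFIIH, may raise repair genes without p53.

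Other splits of the libraries were fitted for each count of the planned comparisons. For 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real counts and the highest of the other splits were 763 and 31 for the male diet, 976 and 3 for Tfb1 RNAi at 0.15 M, and 651 and 1 at 1.0 M. They were 847 and 0 for the cg female diet (by limma, 1048 genes at an unadjusted p under 0.05 in the real one). In r4 w1118 females they were 168 and 1, 311 and 1, and 375 and 2 at 0.3 M, 0.7 M and 1.0 M. The share of splits that called as many was under 0.05 for the dose trend (381 genes, 2 of 100 splits, highest other 390). It was under 0.05 too for the shared female genes (72, 1 of 100, highest other 0). In other comparisons the real split alone of 35 gave as many, the smallest share that 35 splits allow. These were 784 genes for the r4 60100 diet (highest other 407) and 436 and 675 for FOXO RNAi at 0.15 M and 0.7 M (224 and 641). So were 54 and 311 for p53 RNAi (41 and 302) and 78 and 329 for Stat92E RNAi (38 and 110). For FOXO RNAi at 0.7 M and p53 RNAi at both diets another split came close to the real count. The count alone does not exclude chance there.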
